A study of Homo sapiens with 24 samples.

How the data were processed

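RNA sequencing was carried out on ARPE-19 cells, an established human cell line of retinal pigment epithelium. The groups are scramble, Pink1 siRNA, Nrf2 siRNA and Nrf2-Pink1 siRNA (the double siRNA). Each of the 4 groups has 3 biological replicates with 2 technical replicates each, which gives 24 deposited samples. The labels use the words knockout and KD for groups that the series design describes as siRNA; they are treated here as siRNA. The protocols in the labels also describe scratch wounding, and the sources do not say whether the cells used for RNA were wounded.

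Per the labels' protocols, the libraries were stranded and made from mRNA, and reads were paired. The submitters' processing notes name STAR, RSEM and edgeR and the genome builds GRCh37 and hg19. The versions of these tools, and which tool made which value, are not given in the sources used here. The deposited table holds TPM (transcript abundance scaled to the same total in each sample), computed by the authors for 24053 Ensembl gene identifiers, with at most 2 decimals. Each column sums to between 999678 and 999945. TPM does not hold the number of reads, so the depth of each sample is unknown and no interval or detection limit that needs it is given. Of the identifiers, 22789 were found in the gene name table and 19325 have a symbol there; the others are printed as identifiers. No coordinates are given, because the annotation at hand is for another genome build than the one named for the files.

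The TPM of the 2 technical replicates was averaged, which leaves 12 biological samples. Values were taken as log2(TPM + 1), and the 13810 genes with a mean of at least 1 TPM over the 12 samples were tested. A linear model with the 4 groups was fitted per gene with limma 3.58.1 in R 4.3.3, with an intensity trend in the prior (8 residual and 4.93 prior degrees of freedom). Tests were two-sided. A gene is called when its adjusted p (Benjamini-Hochberg over all genes tested) is under 0.05. The comparisons were each siRNA group against scramble, the double siRNA against each single siRNA, Pink1 siRNA against Nrf2 siRNA, and the interaction, which is the double siRNA minus Pink1 siRNA minus Nrf2 siRNA plus scramble on the log2 scale. Folds are computed from the fitted log2 differences of TPM + 1, so they can be smaller than the ratio of the mean TPM for genes at low levels. Group levels are the mean ± SD of TPM over n = 3 biological samples. With 3 samples against 3, a rank or permutation test of a single gene cannot give a two-sided p below 0.1.

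The 23 gene lists are: NRF2 targets; mesenchymal and EMT genes; epithelial junction and keratin genes; RPE identity; TGF-beta pathway; mitophagy and autophagy; nuclear-encoded subunits of oxidative phosphorylation (OXPHOS); genes encoded by mitochondrial DNA; mitochondrial biogenesis and dynamics; mitochondrial antioxidant and redox genes; mitochondrial chaperones and proteases; ATF4 and the integrated stress response; apoptosis; p53 targets; PI3K and AKT pathway; cell cycle; interferon-stimulated genes; NF-kB and cytokines; cholesterol synthesis; glycolysis and hypoxia; complement and lipoprotein genes; cytosolic ribosomal proteins; and markers of blood, endothelial, neural and photoreceptor cells. None of the 13 genes encoded by mitochondrial DNA was found in the table, so that list is not analysed here, and 22 lists were tested. Shorter names used below, such as complement genes or glycolysis genes, stand for the whole list as named here. The test was limma's camera with a preset correlation between genes of 0.01, which compares the genes of a list with all other genes; p was adjusted over the 22 lists within a comparison. It was repeated with the correlation estimated from the data. For the setting with 24 samples, the form for precomputed statistics (cameraPR) was used on the z-scores of the moderated statistics.

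The named genes follow a rule. It names NFE2L2 and PINK1. For each comparison with scramble it names the 12 called genes with the largest rise and the 12 with the largest fall among those with a mean of at least 5 TPM and all 3 siRNA samples on the same side of all 3 scramble samples. For the other comparisons it takes 5 per direction. For each list it names up to 4 called members with the smallest adjusted p, or the 2 members with the highest mean TPM where none was called. VIM, CDH1, ZEB1, SNAI1, TXNRD1, TXNRD2, NQO1, HMOX1, BAX and BCL2 are named wherever their list is described. Some genes that the rule names are not reported here. Genes named outside this rule were chosen after their values were seen, and are marked so. The grouping, comparisons, tests, lists, naming rule and all alternatives but a pair were fixed before the data were examined.

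The alternatives planned were other pseudocounts (0.1 and 5), no filter, a minimum of 5 TPM, median-of-ratios rescaling, quantile normalization, a fit with the compared groups alone, the replicate number as a block, each technical replicate alone, all 24 samples with the biological sample as a random effect (duplicateCorrelation), sample weights (arrayWeights), an added minimum of 1.5-fold, limma's treat against 1.2-fold, the estimated correlation for lists, and leaving out each biological sample in turn. A pair of alternatives was added after seeing the data: removing the most abundant gene and rescaling the rest, and leaving the double-siRNA samples out of the fit.

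Comparisons that share the scramble samples move together even without any effect. The correlation and covariance of their fold changes across genes, and the numbers of shared calls, were therefore set against 100 simulations without effect, made by mixing the residuals of the samples with random normal weights around each gene's mean. The method was also tested on data simulated with normal noise, drawn independently for each gene and sample at the fitted SD of the gene. Whole samples also differ in the real data, so the rates may not hold there. Genes shifted by 1.5-fold were called in 4.48% to 13.4% of cases in the comparisons of groups and in 0 of 67 for the interaction. Genes shifted by 2-fold were called in 47.8% to 59.7% of cases and in 13.4% for the interaction, and genes shifted by 4-fold in 89.4% to 93.9% and 72.7%. In the same data 3 to 8 unshifted genes were called per comparison. Splits of the samples that ignore the groups were fitted in the same way. All 12 samples are in the results given unless a sample is named as left out.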

Results

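Gene expression was measured by RNA sequencing in ARPE-19 cells given scramble siRNA, Pink1 siRNA, Nrf2 siRNA or the double Nrf2-Pink1 siRNA, with 3 biological samples per group. Values are TPM (transcript abundance scaled to the same total in each sample), and the depth behind them is unknown. On the log2 scale, single technical replicates correlated across genes with r of 0.942 to 0.971. Biological samples, each averaged over its technical replicates, correlated with r of 0.940 to 0.965 within a group and 0.931 to 0.964 between groups. Averaging raises r, so the technical and biological r are not like for like. For the 4935 genes with a mean of at least 20 TPM, the median SD was 0.117 between technical replicates and 0.247 between biological samples. A single identifier without an entry in the name table, ENSG00000226958, took 15.5% of all TPM in double-siRNA replicate 3 and 41.4% in double-siRNA replicate 1. The other 10 samples lay between 24.9% and 38.6%.

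The first question was whether each siRNA lowered its own target. PINK1 (ENSG00000158828), a kinase that marks damaged mitochondria, stood at 55.8 ± 1.93 TPM (SD, n = 3) with scramble. It was at 14.6 ± 3.22 TPM with Pink1 siRNA, 26.2% of the scramble mean (adjusted p = 0.00056), and at 18.7 ± 2.93 TPM with the double siRNA, 33.5% (adjusted p = 0.00301). With Nrf2 siRNA it was at 57.2 ± 8.35 TPM (log2 fold change 0.027, SE 0.175, adjusted p = 0.976). NFE2L2 (ENSG00000116044), which encodes the antioxidant transcription factor NRF2, stood at 80.7 ± 7.69 TPM with scramble. It was at 20.025 ± 7.72 TPM with Nrf2 siRNA, 24.8% of scramble (adjusted p = 0.00523), and at 28.9 ± 6.16 TPM with the double siRNA, 35.8% (adjusted p = 0.0212). With Pink1 siRNA it was at 68.7 ± 4.02 TPM (log2 fold change -0.23, adjusted p = 0.763). The call of NFE2L2 with the double siRNA ended without scramble replicate 1, 2 or 3 (log2 fold change -1.39, -1.52 and -1.49 against -1.47), without double-siRNA replicate 2 (-1.51) and with technical replicate 1 alone (-1.48). With the compared groups alone in the fit, NFE2L2 was called with neither Nrf2 siRNA nor the double siRNA and PINK1 was not called with the double siRNA, at log2 fold changes of -2.03, -1.47 and -1.54.

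**Figure D1:**
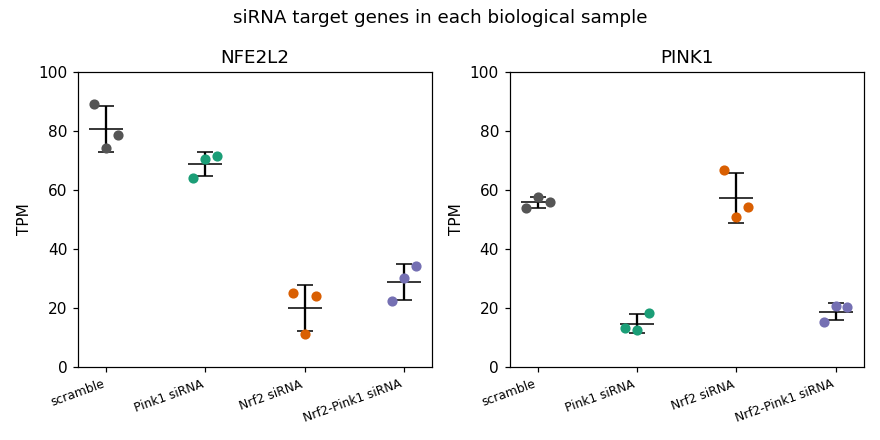
TPM of NFE2L2 and PINK1 in the 4 groups; points are the 3 biological samples, and bars show the mean ± SD. PINK1 is at 14.6 TPM with Pink1 siRNA and 18.7 TPM with the double siRNA, and NFE2L2 at 20.025 TPM with Nrf2 siRNA and 28.9 TPM with the double siRNA.

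Pink1 siRNA was compared with scramble to ask what accompanies a lower level of PINK1 message. HMCN1, an extracellular matrix protein, rose from 7.33 ± 2.65 to 43.3 ± 8.72 TPM (n = 3 each; 5.46-fold, log2 SE 0.260, adjusted p = 0.00128). TYRP1, an enzyme of melanin synthesis, rose from 9.91 ± 1.70 to 45.5 ± 6.70 TPM (4.27-fold, log2 SE 0.192, adjusted p = 0.00056). The amino acid transporter SLC7A8 rose from 17.0 ± 3.02 to 67.0 ± 13.1 TPM, the cytokine IL33 from 3.995 ± 0.999 to 17.4 ± 6.82 TPM, and ceruloplasmin (CP), a copper-carrying ferroxidase, from 10.9 ± 2.94 to 35.0 ± 3.07 TPM. CHRDL1, a secreted BMP antagonist, fell from 54.2 ± 2.63 to 19.1 ± 0.597 TPM (adjusted p = 0.00534), and CLDN1, a tight junction protein, from 35.9 ± 3.37 to 17.1 ± 1.41 TPM (adjusted p = 0.0289). Over 6 leave-outs limma called CLDN1 in 0, IL33 in 1, and HMCN1, TYRP1, SLC7A8, CP and CHRDL1 in 6. Other rises were those of PDZRN3, CDKL1, TSPAN10, FBN2, MYO7A, NELL2 and ABCB5, with log2 fold changes from 1.42 to 1.16. Other falls were those of PINK1, ENSG00000261604, MAMDC2, ITGBL1, AOX1, CTSO, PON2, NEK7, NEDD4 and FIBIN, with log2 fold changes from -1.88 to -0.94.

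In all, 65 of 13810 genes were called with Pink1 siRNA, 49 higher and 16 lower, 45 of them by at least 2-fold. The groups were apart in all 65; over all tested genes they were apart in 25.0%, where chance gives 10%. Leaving out scramble replicate 1, 2 or 3 left 26, 22 and 22 calls, and leaving out Pink1 siRNA replicate 1, 2 or 3 left 40, 24 and 24. The higher and lower genes numbered 107 and 64 after median-of-ratios rescaling (62.6% higher, against 75.4%) and 90 and 87 with ENSG00000226958 removed (50.8% higher), and 149 genes were called with the double-siRNA samples out of the fit.

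Among the lists, 5 passed with Pink1 siRNA at the preset correlation; with an estimated correlation the adjusted p was 0.871 for each of them. Of the 14 RPE identity genes, TYR and TYRP1 rose and 12 did not pass (list adjusted p = 0.00433); adjusted over the list alone, 3 rose. TYR, the first enzyme of melanin synthesis, went from 0.402 ± 0.183 to 3.71 ± 0.354 TPM. None of the 75 OXPHOS genes passed alone, but the list was lower (mean log2 fold change -0.18, adjusted p = 0.000113). ATP5F1B stood at 536 ± 4.92 and 593 ± 92.1 TPM and COX7C at 416 ± 43.2 and 406 ± 11.9 TPM. The 25 interferon-stimulated genes were lower as a list (mean -0.95, adjusted p = 2.82e-07) with 0 passing alone by limma over all genes or adjusted over the list alone, as were the 24 cholesterol synthesis genes (mean -0.17, adjusted p = 0.0217; 1 fell when adjusted over the list alone). IFI6 stood at 898 ± 564 and 219 ± 79.4 TPM, FDPS at 179 ± 10.9 and 169 ± 20.1 TPM and FDFT1 at 143 ± 9.52 and 132 ± 9.85 TPM. The 51 cytosolic ribosomal protein genes were higher (mean 0.26, adjusted p = 2.79e-05), with RPS2 at 3103 and 4574 TPM and RPS3 at 2195 and 3006 TPM. That list was highest in Pink1 siRNA replicate 3 (0.43 above the scramble mean), which held the lowest share of ENSG00000226958 in these groups (24.9%). Scramble replicate 1 lay level with the Pink1 siRNA samples in the interferon genes: without it the list mean was -1.52, and without scramble replicate 2 it was -0.63. Without scramble replicate 1 the cholesterol list was no longer called (mean -0.16), nor with technical replicate 1 alone (-0.14). With the minimum of 5 TPM the RPE identity list was not called (mean 0.35).

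Nrf2 siRNA was compared with scramble to ask what accompanies a lower level of NFE2L2 message; the NRF2 protein was not measured. NQO1, a quinone reductase and classic NRF2 target, fell from 160 ± 6.67 to 44.5 ± 4.79 TPM (n = 3 each; log2 fold change -1.83, SE 0.168, adjusted p = 0.000489). IGFBP5, a secreted binding protein of insulin-like growth factors, rose from 11.2 ± 0.929 to 51.3 ± 7.88 TPM (4.27-fold, log2 SE 0.149, adjusted p = 4.69e-05). CA9, a hypoxia-induced carbonic anhydrase, rose from 118 ± 18.3 to 345 ± 94.0 TPM (adjusted p = 0.0236), and the gap junction protein GJA1 fell from 147 ± 18.6 to 49.1 ± 16.6 TPM (adjusted p = 0.0236). SCG2, a protein of secretory granules, fell from 11.3 ± 1.84 to 2.11 ± 0.450 TPM, and IDH2, a mitochondrial isocitrate dehydrogenase, from 49.9 ± 3.70 to 23.6 ± 4.37 TPM. Further rises were those of SCHIP1 (2.34), SPAG4, CP, PFKFB4, GBP1, FGF1, C1R, H2BC12, TYRP1 and ABCB5, the last 9 with log2 fold changes from 1.83 to 1.15. Further falls were those of NFE2L2, AKR1C3, APIP, TRIM47, LAMTOR1, ECHDC1, DCTN5 and AVPI1, from -2.03 to -0.89. H2BC12 and AKR1C3 belong to families of near-identical genes, and TPM does not show how shared reads were assigned.

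With Nrf2 siRNA 46 genes were called, 30 higher and 16 lower, 30 of them by at least 2-fold. The groups were apart in all 46 and in 22.9% of all tested genes, where chance gives 10%. Without scramble replicate 1, 2 or 3 the count was 13, 8 and 10, and without Nrf2 siRNA replicate 2 or 3 it was 9 and 6. It was 148 after median-of-ratios rescaling, 131 with the double-siRNA samples out of the fit and 8 with the compared groups alone.

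NRF2 targets were lower as a list with Nrf2 siRNA (adjusted p = 1.72e-09; adjusted p = 0.405 with an estimated correlation). Of 26 tested, NQO1, AKR1C3 and TXNRD1 fell and 23 did not pass; adjusted over the list alone, 7 fell. TXNRD1, a thioredoxin reductase, went from 514 ± 16.2 to 279 ± 31.1 TPM, and HMOX1, the heme oxygenase, stood at 10.8 ± 2.34 and 8.72 ± 2.75 TPM. The mesenchymal list was higher (adjusted p = 4.73e-05; adjusted p = 0.415 with an estimated correlation): of 20, MMP2, LOX and THBS1 rose, and 5 when adjusted over the list alone. MMP2, a matrix protease, went from 38.8 ± 3.15 to 86.0 ± 6.63 TPM and LOX, which crosslinks collagen, from 347 ± 44.3 to 639 ± 67.9 TPM. Over 6 leave-outs limma called MMP2 in 6, and LOX and THBS1 in 0. VIM stood at 4297 and 5129 TPM and ZEB1 at 8.23 ± 1.04 and 10.5 ± 1.37 TPM. CDH1 and SNAI1 were below the minimum for testing, with means of at most 0.34 TPM in any group.

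Of the 28 glycolysis and hypoxia genes, CA9, EGLN3 and PFKFB4 rose with Nrf2 siRNA, and 17 rose when adjusted over the list alone (list adjusted p = 8.74e-15; adjusted p = 0.405 with an estimated correlation). Of the 25 interferon-stimulated genes 0 passed by limma over all genes, while 25 rose when adjusted over the list alone (mean 1.83, list adjusted p = 5.96e-18; adjusted p = 0.415 with an estimated correlation). Relative to the scramble mean, the list stood at -1.15, 0.64 and 0.52 in scramble replicates 1 to 3 and at 0.85, 2.86 and 1.77 in those of Nrf2 siRNA. The macrophage marker CD68 also rose over its list alone (adjusted p = 0.0215). IFI6 stood at 898 ± 564 TPM with scramble and 2336 ± 846 TPM with Nrf2 siRNA. TYR and TYRP1 rose among the 14 RPE identity genes, and 3 when adjusted over the list alone (adjusted p = 0.00086; adjusted p = 0.415 with an estimated correlation). Complement genes were higher (18 tested; C1R rose, and 4 over the list alone; adjusted p = 0.00238, and adjusted p = 0.492 with an estimated correlation). C1R, a protease of the classical pathway, went from 219 ± 25.5 to 511 ± 94.7 TPM.

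With no member called over all genes, the OXPHOS list (mean -0.18, adjusted p = 1.63e-05), the cell cycle list (-0.16, adjusted p = 0.00113) and the cholesterol list (-0.23, adjusted p = 0.000152; 1 fell over the list alone) were lower and the PI3K and AKT list was higher (0.13, adjusted p = 0.0461). With an estimated correlation their adjusted p = 0.754, 0.754, 0.492 and 0.511. The members with the highest levels, with scramble and with Nrf2 siRNA, were ATP5F1B (536 ± 4.92 and 466 ± 27.4 TPM), PCNA (186 ± 15.6 and 169 ± 4.39 TPM), FDPS (179 ± 10.9 and 141 ± 24.6 TPM) and AKT1 (55.8 ± 2.29 and 75.8 ± 7.23 TPM). AKT1 did not pass over its list alone with Nrf2 siRNA (limma adjusted p = 0.130). It did with Pink1 siRNA (81.5 ± 8.12 TPM, adjusted p = 0.0145) and the double siRNA (83.1 ± 2.55 TPM, adjusted p = 0.00926). Without Nrf2 siRNA replicate 2 the means of the OXPHOS and cholesterol lists were -0.077 and -0.11, and without Nrf2 siRNA replicate 1 that of the OXPHOS list was -0.28. The PI3K and AKT list was not called without scramble replicate 3 (mean 0.090) or Nrf2 siRNA replicate 2 or 3 (0.12 and 0.11), nor with the replicate block, either technical replicate alone, sample weights or ENSG00000226958 removed.

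The double siRNA was compared with scramble. FN1, the fibronectin of the extracellular matrix, rose from 378 ± 16.4 to 881 ± 306 TPM (n = 3 each; 2.24-fold, log2 SE 0.229, adjusted p = 0.034). Its call held in 1 of 6 leave-outs. AMTN, a secreted matrix protein, rose from 5.26 ± 2.40 to 31.9 ± 16.4 TPM (5.02-fold, log2 SE 0.339, adjusted p = 0.00856), and IGFBP5 from 11.2 ± 0.929 to 51.2 ± 4.30 TPM (4.29-fold, log2 SE 0.149, adjusted p = 4.51e-05). P3H1, a prolyl hydroxylase that modifies collagen, rose from 27.8 ± 0.718 to 74.0 ± 7.20 TPM, and CA9 from 118 ± 18.3 to 350 ± 123 TPM. NQO1 fell from 160 ± 6.67 to 60.3 ± 13.0 TPM (adjusted p = 0.00301), CHRDL1 from 54.2 ± 2.63 to 18.3 ± 6.16 TPM and GJA1 from 147 ± 18.6 to 54.5 ± 17.4 TPM.

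Further rises with the double siRNA were those of SPAG4, HMCN1, TYRP1, YBX3, SLC22A3, MEIS3 and BACE2, with log2 fold changes from 1.72 to 1.17. Further falls were those of ENSG00000271043, SCARNA1, SCG2, PINK1, ENSG00000261604, ACYP2 and NFE2L2, from -1.67 to -1.47. SMIM10L1 was called lower and is listed at 0 in all 3 double-siRNA samples, and at 10.5, 28.7 and 5.47 TPM in scramble replicates 1 to 3. RNU4ATAC, a small nuclear RNA of the minor spliceosome, was called lower; it was at 24.1 TPM in double-siRNA replicate 1 and listed at 0 in replicates 2 and 3, against 47.4 to 121 TPM with scramble. RNU4ATAC and SCARNA1 are small RNAs without the long tail that mRNA selection uses, and a 0 without counts does not show absence.

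**Figure D2:**
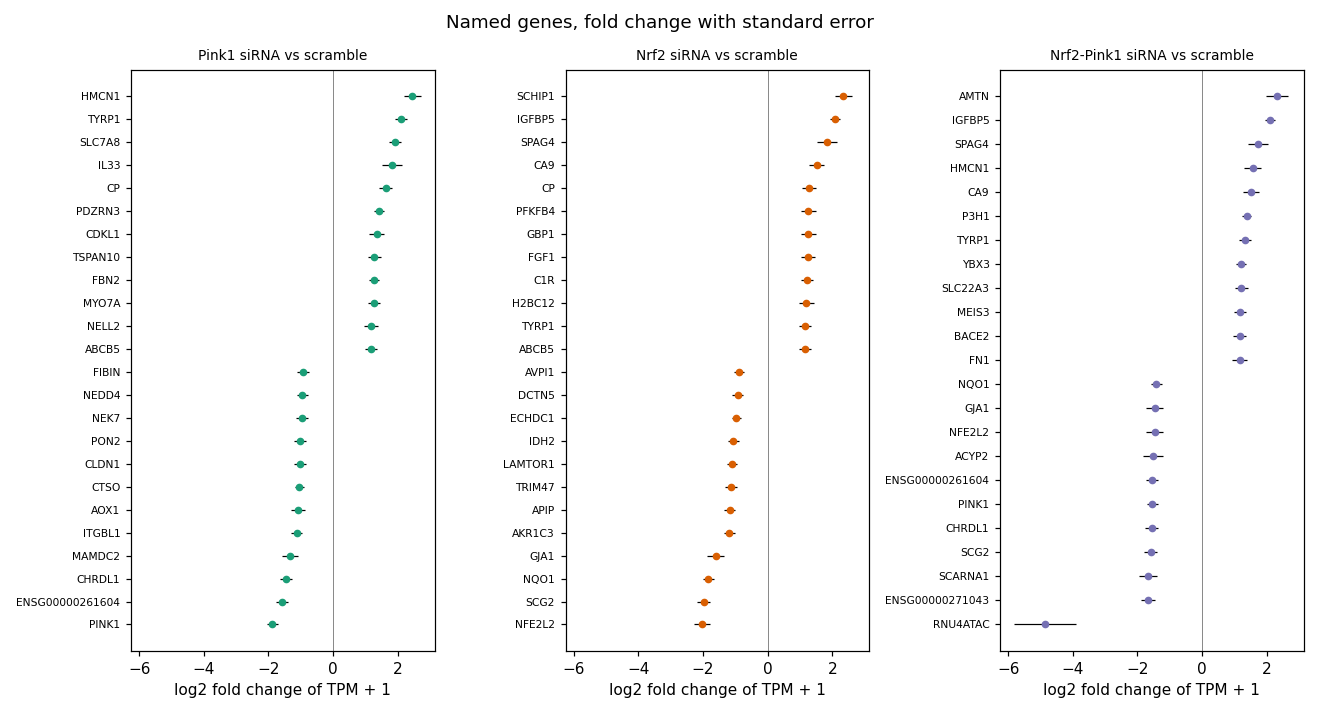
Fitted log2 fold changes against scramble (points) with their SE (lines) for the genes named by rule in the comparisons of Pink1 siRNA, Nrf2 siRNA and the double siRNA. SMIM10L1, listed at 0 in all double-siRNA samples, is left out; IGFBP5 reaches 2.09 with Nrf2 siRNA and 2.10 with the double siRNA.

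The double siRNA gave 104 called genes, 65 higher and 39 lower, 52 by at least 2-fold. The groups were apart in all 104 and in 18.1% of all tested genes (10% by chance). Without scramble replicate 1, 2 or 3 the count was 37, 23 and 19, and without double-siRNA replicate 1 or 2 it was 240 and 66. It was 333 after median-of-ratios rescaling, 321 with ENSG00000226958 removed (135 higher and 186 lower, 42.1% higher against 62.5%) and 6 with the compared groups alone. The main fit pools the spread over the 4 groups. With the double-siRNA samples out of it, 149 genes in place of 65 were called for Pink1 siRNA against scramble. If the double-siRNA samples spread more than the others, their p-values in the pooled fit are too small. The spread per group was not tested.

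Mesenchymal genes were higher as a list with the double siRNA (adjusted p = 3.37e-09; adjusted p = 0.494 with an estimated correlation). Of 20, MMP2, THBS1, LOX and FN1 rose. Adjusted over the list alone, 12 rose and 1 fell. Over 6 leave-outs MMP2 was called in 3, and THBS1, LOX and FN1 in 1 each. MMP2 was at 66.2 ± 4.06 TPM and THBS1, a matrix glycoprotein, at 257 ± 27.6 TPM, against 38.8 ± 3.15 and 155 ± 12.2 TPM with scramble. VIM stood at 6091 TPM (SD 1732) and ZEB1 at 10.6 ± 2.10 TPM. Neither passed over all genes, and VIM rose when adjusted over the list alone (adjusted p = 0.0477). Of 26 NRF2 targets NQO1 and AKR1C3 fell, and 7 when adjusted over the list alone (list adjusted p = 0.000291; adjusted p = 0.730 with an estimated correlation). TXNRD1 was at 346 ± 41.5 TPM and HMOX1 at 9.11 ± 1.11 TPM. Neither passed over all genes, and TXNRD1 fell when adjusted over the list alone (adjusted p = 0.00869). Without double-siRNA replicate 1 the mean of the NRF2 list was -0.15 against -0.28. Of the 28 glycolysis and hypoxia genes CA9 and P4HA2 rose, and 15 when adjusted over the list alone (adjusted p = 2.33e-11; adjusted p = 0.637 with an estimated correlation). TYR and TYRP1 rose among 14 RPE identity genes, and 4 when adjusted over the list alone (adjusted p = 0.000758; adjusted p = 0.652 with an estimated correlation). With the minimum of 5 TPM the RPE identity list was not called (mean 0.28 against 0.45).

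The remaining lists called with the double siRNA had an adjusted p = 0.886 with an estimated correlation. OXPHOS genes were lower (mean -0.20, 0 of 75 called, adjusted p = 0.000234), with ATP5F1B at 569 ± 127 TPM and COX7C at 376 ± 151 TPM. Ribosomal protein genes were higher (mean 0.33, adjusted p = 4.04e-08); of 51, RPLP0 rose, also when adjusted over the list alone, from 1691 ± 89.5 to 3506 TPM (SD 1025). ATF4 genes were higher (0.18, adjusted p = 0.0361), with DDIT4, an inhibitor of mTORC1 induced by stress, up from 21.4 ± 1.83 to 40.8 ± 3.43 TPM as the only call of 21. The complement and lipoprotein list was higher by camera (0.26, adjusted p = 0.0443). Its only call of 18 over all genes was TIMP3, an inhibitor of matrix proteases, up from 186 ± 21.2 to 359 ± 63.9 TPM. Over the list alone TIMP3 was 1 of 2. The OXPHOS list was not called without double-siRNA replicate 1 (mean -0.017), the ATF4 list without scramble replicate 1 (0.16) or double-siRNA replicate 3 (0.057), and the complement list without double-siRNA replicate 3 (0.10). Both calls also ended with quantile normalization (0.17 and 0.22), technical replicate 2 alone and sample weights. That of the ATF4 list ended with ENSG00000226958 removed (0.078), and that of the complement list with the minimum of 5 TPM (0.20) and the compared groups alone. Without double-siRNA replicate 3 the ribosomal mean was 0.11 and the OXPHOS mean -0.39. That sample held the lowest share of ENSG00000226958 (15.5%). Without double-siRNA replicate 1 the ribosomal mean was 0.53, the ATF4 mean 0.29 and the complement mean 0.40. Interferon-stimulated genes were not called (mean -0.058, adjusted p = 0.705) except without scramble replicate 1 (-0.63).

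**Figure D3:**
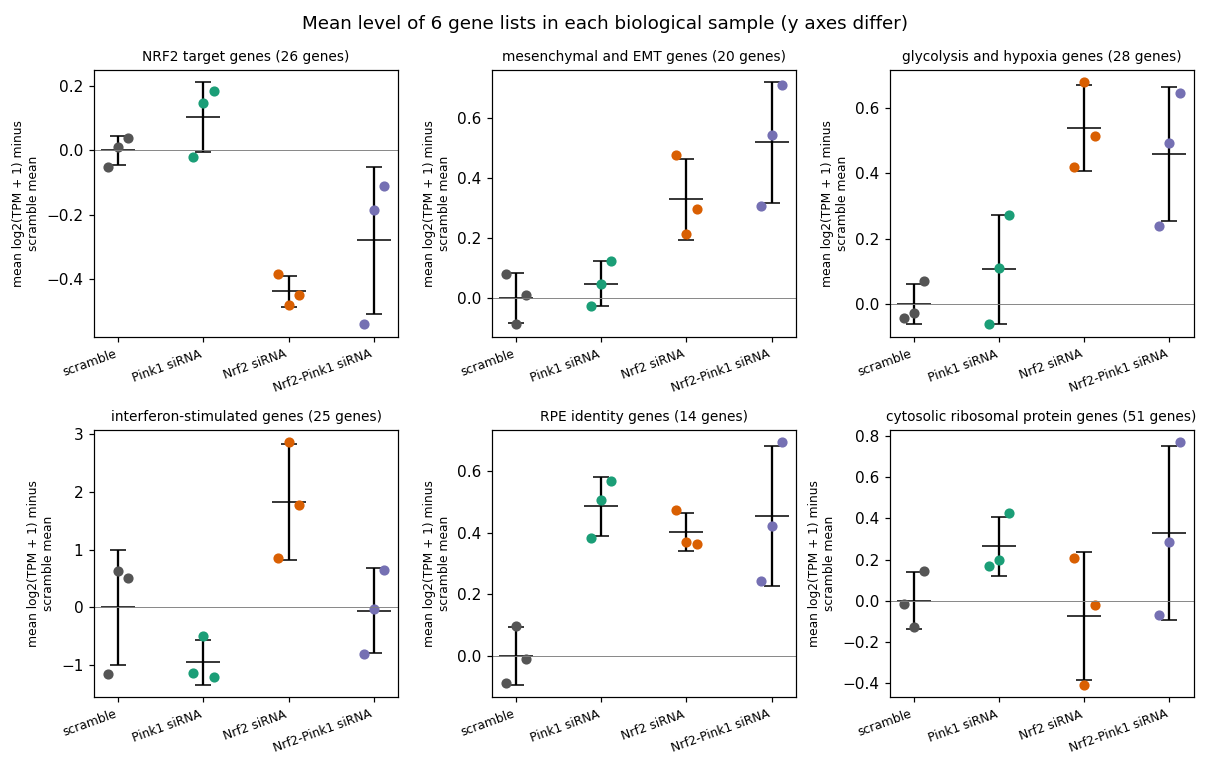
Mean log2(TPM + 1) over the genes of 6 lists in each sample, minus the scramble mean; points are the 3 biological samples of a group, and bars show the mean ± SD. For interferon-stimulated genes, Nrf2 siRNA samples lie at 0.85, 2.86 and 1.77, Pink1 siRNA samples at -1.14, -0.50 and -1.21, and scramble replicate 1 at -1.15.

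The comparisons with scramble share their controls. Called in all of them were 7 genes, each higher: ABCB5, YBX3, TYR, TYRP1, IGFBP5, P3H1 and SRPRA, of which SRPRA was chosen after its values were seen. Pink1 siRNA and Nrf2 siRNA shared 8 higher genes (expected 49 × 30 / 13810 = 0.106) and 0 lower genes by limma (expected 0.0185 if independent). Median-of-ratios rescaling gave 27 higher and 4 lower for this pair. In the main fit each had 1687 genes at an unadjusted p under 0.05. Pink1 siRNA and the double siRNA shared 25 higher (expected 0.231) and 5 lower (0.0452), and Nrf2 siRNA and the double siRNA 19 higher (0.141) and 10 lower (0.0452). These expectations take the comparisons as independent, which they are not. Simulations without effect gave means of 0, 0 and 8.92 shared higher genes and 0.01, 0 and 2.55 shared lower genes for the same pairs. The means of 8.92 and 2.55 each came from 1 of 100 simulations. Those simulations hold no changed gene, so they do not give the overlap due to shared controls at the real numbers of calls. Across genes, which are not independent replicates, fold changes correlated with r = 0.483, 0.638 and 0.592, and simulations without effect gave a mean r of 0.465, 0.429 and 0.464. Covariances were 0.0835, 0.114 and 0.109 against 0.0598, 0.0550 and 0.0605 in the simulations, differences of 0.0237, 0.0586 and 0.0490 beside an SD between simulations of 0.0533, 0.0480 and 0.0562.

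The double siRNA was compared with each single siRNA. The shared target also tended to be lowered less by the double siRNA, though limma called neither difference. NFE2L2 had a log2 fold change of 0.57 against Nrf2 siRNA (SE 0.254), and PINK1 0.34 against Pink1 siRNA (SE 0.175). A weaker lowering of the shared target cannot be told apart here from an effect of the added siRNA. Against Pink1 siRNA, NQO1 fell from 173 ± 20.8 to 60.3 ± 13.0 TPM (n = 3 each; log2 fold change -1.52, SE 0.168, adjusted p = 0.00811), SCG2 from 11.03 ± 2.09 to 3.10 ± 0.810 TPM (-1.56) and BCAT1, an aminotransferase of branched-chain amino acids, from 54.5 ± 0.518 to 24.7 ± 6.79 TPM (-1.14). MMP2 rose from 32.6 ± 1.79 to 66.2 ± 4.06 TPM (0.998, SE 0.128, adjusted p = 0.0201), IGFBP5 from 24.6 ± 2.33 to 51.2 ± 4.30 TPM (1.03) and ITGBL1 from 15.1 ± 1.68 to 35.1 ± 7.29 TPM (1.15). These 6 genes, 3 higher and 3 lower, were all that was called, and their groups were apart (8.85% of all tested genes; 10% by chance). NFE2L2, the target of the added siRNA, was lower by a log2 fold change of -1.24 but not called (adjusted p = 0.165). The count was 2, 1 and 2 without Pink1 siRNA replicate 1, 2 or 3 and 16 without double-siRNA replicate 1. It was 13 after median-of-ratios rescaling (8 higher and 5 lower, 61.5% against 50.0%), 21 with ENSG00000226958 removed, and 0 by limma with the compared groups alone, where 801 genes had an unadjusted p under 0.05 in the fit of all groups.

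Against Pink1 siRNA, 6 lists were called for the double siRNA. Of 26 NRF2 targets NQO1 fell, and 8 when adjusted over the list alone (adjusted p = 4.89e-10; adjusted p = 0.280 with an estimated correlation). TXNRD1 stood at 541 ± 38.3 and 346 ± 41.5 TPM and HMOX1 at 12.4 ± 1.99 and 9.11 ± 1.11 TPM. Of 20 mesenchymal genes MMP2 rose, and 9 when adjusted over the list alone (adjusted p = 3.87e-14; adjusted p = 0.161 with an estimated correlation). VIM stood at 4874 and 6091 TPM and ZEB1 at 10.7 ± 0.331 and 10.6 ± 2.10 TPM. Glycolysis genes were higher (mean 0.35, adjusted p = 1.41e-13; adjusted p = 0.319 with an estimated correlation), with 7 of 28 over the list alone and LDHA at 1394 and 2396 TPM. With an adjusted p = 0.898 with an estimated correlation, interferon-stimulated genes were higher (0.89, adjusted p = 1.69e-09; IFI6 at 219 ± 79.4 and 571 ± 287 TPM), complement genes higher (0.17, adjusted p = 0.014; CD59 at 347 ± 15.1 and 461 ± 159 TPM) and cell cycle genes lower (-0.19, adjusted p = 9.77e-05; TYMS at 206 ± 13.7 and 196 ± 79.2 TPM). Without double-siRNA replicate 1 the mean of the NRF2 list was -0.25 against -0.38 and that of the complement list 0.29, and without double-siRNA replicate 3 the interferon mean was 0.53 and the cell cycle mean -0.33. The cell cycle list was not called without double-siRNA replicate 1 (-0.036), nor the complement list without Pink1 siRNA replicate 2 (0.14) or double-siRNA replicate 3 (0.017), nor with quantile normalization, technical replicate 2 alone or sample weights. The ribosomal list, not called here (adjusted p = 0.158), was lower without double-siRNA replicate 3 (-0.16) and higher without Pink1 siRNA replicate 3 (0.15) or double-siRNA replicate 1 or 2 (0.27 and 0.087).

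Against Nrf2 siRNA, the double siRNA called 2 genes, both lower. PINK1 fell from 57.2 ± 8.35 to 18.7 ± 2.93 TPM (n = 3 each; log2 fold change -1.57, SE 0.175, adjusted p = 0.00914) and SCHIP1 from 21.4 ± 9.56 to 4.03 ± 1.18 TPM (-2.10, SE 0.264, adjusted p = 0.0166). Both genes had the groups apart, as did 9.49% of all tested genes (10% by chance). The count was 4 without Nrf2 siRNA replicate 2 or double-siRNA replicate 1, 1 without double-siRNA replicate 2, 3 with ENSG00000226958 removed (1 higher and 2 lower), and 0 by limma with the compared groups alone or technical replicate 2 alone, where 960 genes had an unadjusted p under 0.05 in the fit of all groups. PINK1 was called in every leave-out and SCHIP1 was not.

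For the double siRNA against Nrf2 siRNA 4 lists were called. Interferon-stimulated genes were lower (mean -1.89, adjusted p = 2.80e-27; adjusted p = 0.628 with an estimated correlation): 0 of 25 were called by limma over all genes and 25 fell when adjusted over the list alone, with IFI6 at 2336 ± 846 and 571 ± 287 TPM. Ribosomal protein genes were higher (0.41, 51 of 51 with a positive fold change, adjusted p = 8.49e-20), as were NRF2 targets (0.16, adjusted p = 0.0179) and mesenchymal genes (0.19, adjusted p = 0.035); each had an adjusted p = 0.876 with an estimated correlation. NQO1 stood at 44.5 ± 4.79 and 60.3 ± 13.0 TPM, TXNRD1 at 279 ± 31.1 and 346 ± 41.5 TPM, HMOX1 at 8.72 ± 2.75 and 9.11 ± 1.11 TPM, VIM at 5129 and 6091 TPM and ZEB1 at 10.5 ± 1.37 and 10.6 ± 2.10 TPM. The ribosomal mean was 0.24 without Nrf2 siRNA replicate 2 and 0.18 without double-siRNA replicate 3. Over single samples the ribosomal level, relative to the scramble mean, tended to be higher where the share of ENSG00000226958 was lower. It was 0.77 at 15.5% in double-siRNA replicate 3 and -0.41 at 38.6% in Nrf2 siRNA replicate 2, though -0.070 at 41.4% in double-siRNA replicate 1. Whether the list follows that share or the siRNA, here and in the other comparisons, was not tested. Without double-siRNA replicate 1 the NRF2 and mesenchymal means were 0.29 and 0.30, and without double-siRNA replicate 3 the NRF2 mean was 0.074. The NRF2 list was not called without Nrf2 siRNA replicate 3 (0.15) or double-siRNA replicate 2 (0.11), nor the mesenchymal list without Nrf2 siRNA replicate 2 or 3 (0.13 and 0.17) or double-siRNA replicate 2 or 3 (0.18 and 0.096). Both calls ended with the compared groups alone, and that of the mesenchymal list with the minimum of 5 TPM (0.17), quantile normalization (0.11) and technical replicate 1 alone. The number of lists called was 7 without double-siRNA replicate 1 and 2 without double-siRNA replicate 2, and OXPHOS genes were lower without double-siRNA replicate 3 (-0.21) and higher without double-siRNA replicate 1 (0.17).

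Pink1 siRNA was compared directly with Nrf2 siRNA. Interferon-stimulated genes gave the widest gaps: IFITM1 stood at 4.75 ± 3.06 TPM with Pink1 siRNA and 224 ± 202 TPM with Nrf2 siRNA (n = 3 each; log2 fold change -5.00, SE 0.949, adjusted p = 0.0259), BST2 at 6.82 ± 2.03 and 173 ± 128 TPM (-4.25), and IFI27 at 6.76 ± 0.694 and 161 ± 131 TPM (-4.02). MX1 (-3.77) and OAS2 (-3.69) were lower too. Over 6 leave-outs limma called IFITM1, IFI27 and MX1 in 1 each, OAS2 in 2 and BST2 in 4. The genes named next were called in 6 each. NQO1 was higher with Pink1 siRNA, at 173 ± 20.8 against 44.5 ± 4.79 TPM (1.94, SE 0.168, adjusted p = 0.000384), as were IL33 (2.13), SCG2 (1.95), HMCN1 (1.84) and NFE2L2 (1.81). In all 137 genes were called, 53 higher and 84 lower, 92 by at least 2-fold, all with the groups apart (18.8% of all tested genes; 10% by chance). The count was 44, 53 and 35 without Pink1 siRNA replicate 1, 2 or 3 and 38 without Nrf2 siRNA replicate 2 or 3. It was 296 after median-of-ratios rescaling and 5 with the compared groups alone.

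Between Pink1 siRNA and Nrf2 siRNA, 12 of 25 interferon-stimulated genes were lower with Pink1 siRNA, and 25 when adjusted over the list alone (mean -2.78, adjusted p = 1.66e-36; adjusted p = 0.163 with an estimated correlation). The smallest adjusted p were those of IFI6 (219 ± 79.4 against 2336 ± 846 TPM), OAS2, OAS1 and IFI44. Of 26 NRF2 targets NQO1, TXNRD1, SLC48A1 and AKR1C3 were higher, and 10 over the list alone (adjusted p = 1.17e-12; adjusted p = 0.163 with an estimated correlation). HMOX1 stood at 12.4 ± 1.99 against 8.72 ± 2.75 TPM. Of 20 mesenchymal genes MMP2 and THBS1 were lower, and 4 over the list alone (adjusted p = 0.000123; adjusted p = 0.551 with an estimated correlation). VIM stood at 4874 against 5129 TPM and ZEB1 at 10.7 ± 0.331 against 10.5 ± 1.37 TPM. Of 28 glycolysis and hypoxia genes EGLN3 and PFKFB4 were lower, and 10 over the list alone. By camera the list had an adjusted p = 2.46e-11, and adjusted p = 0.459 with an estimated correlation.

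Complement genes were lower with Pink1 siRNA than with Nrf2 siRNA (C3 called of 18, and 4 over the list alone; adjusted p = 0.00523, and adjusted p = 0.640 with an estimated correlation), with C3 at 13.6 ± 3.72 against 35.2 ± 1.98 TPM. Cell cycle genes were higher (mean 0.29, 32 of 32 with a positive fold change, adjusted p = 1.16e-07; adjusted p = 0.609 with an estimated correlation), as were ribosomal protein genes (0.34, adjusted p = 9.27e-11; adjusted p = 0.810 with an estimated correlation) and mitochondrial antioxidant genes (0.15, adjusted p = 0.0416; adjusted p = 0.875 with an estimated correlation), with no member called. TYMS stood at 206 ± 13.7 against 165 ± 7.38 TPM, RPS3 at 3006 against 2134 TPM, PRDX5 at 289 against 260 TPM and TXNRD2 at 21.5 ± 3.97 against 17.0 ± 1.42 TPM. Without Nrf2 siRNA replicate 2 the ribosomal mean was 0.17. That sample held the highest share of ENSG00000226958 in these groups (38.6%). The antioxidant list was not called without Pink1 siRNA replicate 3 (0.078) or Nrf2 siRNA replicate 2 or 3 (0.064 and 0.17), nor with the minimum of 5 TPM, quantile normalization, technical replicate 1 alone or sample weights.

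The interaction asks whether the double siRNA differs from the sum of the single siRNAs on the log2 scale. The targets themselves had interaction values of 0.79 (NFE2L2) and 0.31 (PINK1), neither called. A weaker lowering of the targets by the double siRNA therefore cannot be told apart from an interaction. By limma 0 genes were called, with a smallest adjusted p of 0.0558 and 753 genes at an unadjusted p under 0.05; the median SE was 0.305. Median-of-ratios rescaling, quantile normalization and removal of ENSG00000226958 each gave 2, the minimum of 5 TPM 3, all 24 samples 28 and sample weights 504. The 24 samples add technical replicates but no biological sample, and the estimation of the weights stopped before it converged. Leaving out scramble replicate 1 or double-siRNA replicate 1 gave 4 each, and leaving out scramble replicate 2 or 3, Pink1 siRNA replicate 2, Nrf2 siRNA replicate 2 or double-siRNA replicate 3 gave 1 each.

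For the interaction 5 lists were called, each with an adjusted p = 0.790 with an estimated correlation. RPE identity genes (mean -0.43, adjusted p = 0.00987; 2 of 14 fell over the list alone) and interferon-stimulated genes (-0.94, adjusted p = 0.000307) lay below the sum of the single siRNAs. OXPHOS (0.17, adjusted p = 0.000307), cholesterol synthesis (0.26, adjusted p = 0.000307) and ribosomal protein genes (0.14, adjusted p = 0.00987) lay above it. The members with the highest levels had interaction values of -0.090 for RDH10, -0.30 for IFI6, 0.13 for ATP5F1B, 0.36 for FDPS and -0.085 for RPS2, and none passed. The RPE identity list was not called without double-siRNA replicate 1 (-0.33), the interferon list without scramble replicate 1 (-0.36) or Nrf2 siRNA replicate 2 (-0.40), and the OXPHOS list without Nrf2 siRNA replicate 2 (0.058) or double-siRNA replicate 3 (-0.028). The ribosomal list was not called without scramble replicate 3 (0.069), Pink1 siRNA replicate 2 (0.11), Nrf2 siRNA replicate 2 (-0.027) or double-siRNA replicate 3 (-0.081), nor with sample weights (0.096). The RPE identity call also ended with no filter (-0.27), the minimum of 5 TPM (-0.34) and technical replicate 1 alone (-0.36). Still called, the OXPHOS mean was 0.10 without scramble replicate 3, 0.26 without Nrf2 siRNA replicate 1 and 0.35 without double-siRNA replicate 1. The interferon mean was -1.42 and -0.56 without the same Nrf2 siRNA and double-siRNA samples, and the cholesterol mean 0.14 without Nrf2 siRNA replicate 2. The ribosomal mean was 0.092 and 0.22 without Pink1 siRNA replicate 1 and 3, 0.28 without Nrf2 siRNA replicate 1 and 0.34 without double-siRNA replicate 1. The number of lists called was 9 without Nrf2 siRNA replicate 1 and 2 without Nrf2 siRNA replicate 2.

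Of the 22 lists, 9 were called in no comparison, though single members of some were. Some were tested on few members: 9 of 23 epithelial junction genes, 7 of 20 NF-kB and cytokine genes and 4 of 25 markers of other cell types. For these the lack of a call says little. For Pink1 siRNA, Nrf2 siRNA and the double siRNA against scramble, the adjusted p was 0.313, 0.0744 and 0.683 for epithelial junction genes, 0.546, 0.679 and 0.679 for the TGF-beta pathway, 0.605, 0.622 and 0.980 for mitophagy, and 0.313, 0.361 and 0.418 for mitochondrial biogenesis. It was 0.890, 0.499 and 0.916 for mitochondrial chaperones, 0.313, 0.513 and 0.928 for apoptosis, 0.313, 0.788 and 0.714 for p53 targets, 0.264, 0.788 and 0.418 for NF-kB and cytokines, and 0.319, 0.788 and 0.418 for markers of other cell types. CLDN1 fell with Pink1 siRNA, while KRT7 stood at 1507 TPM with scramble, 1583 with Pink1 siRNA, 1353 with Nrf2 siRNA and 1822 with the double siRNA. PPARGC1A, a coactivator of mitochondrial biogenesis, rose with Pink1 siRNA from 1.62 ± 0.450 to 5.48 ± 2.04 TPM (adjusted p = 0.0318), and HRK, a pro-apoptotic BH3-only protein, from 13.4 ± 1.12 to 23.9 ± 1.16 TPM (adjusted p = 0.0491). BAX stood at 58.3 ± 6.44 TPM with scramble, 60.5 ± 8.92 with Pink1 siRNA, 58.4 ± 8.91 with Nrf2 siRNA and 54.3 ± 16.1 with the double siRNA, and BCL2 at 2.33 ± 1.54, 3.13 ± 0.727, 2.17 ± 0.361 and 2.94 ± 1.28 TPM. MDM2, which targets p53 for degradation, fell with the double siRNA from 88.0 ± 13.4 to 47.7 ± 13.0 TPM (adjusted p = 0.0453). Over 6 leave-outs limma called CLDN1, PPARGC1A and HRK with Pink1 siRNA in 0, and MDM2 with the double siRNA in 1. Between Pink1 siRNA and Nrf2 siRNA, CCNG1 (262 ± 32.4 against 112 ± 27.3 TPM) and the tubulin TUBB3 (64.4 ± 13.1 against 29.3 ± 3.39 TPM) were higher with Pink1 siRNA, while the macrophage marker CD68 stood at 30.3 ± 9.80 TPM with scramble and 66.6 ± 33.5 TPM with Nrf2 siRNA and did not pass (adjusted p = 0.189). Over the list alone, CD68 rose (adjusted p = 0.0215) and TUBB3 fell (0.0283) with Nrf2 siRNA, and TUBB3 rose with Pink1 siRNA (0.00807). In the mitophagy list SQSTM1 stood at 559 ± 11.5, 596 ± 80.8, 539 ± 26.5 and 578 ± 86.1 TPM in scramble, Pink1 siRNA, Nrf2 siRNA and the double siRNA. In the same order TGFB2 stood at 144 ± 6.31, 126 ± 13.0, 171 ± 34.3 and 170 ± 27.7 TPM, HSPD1 at 397 ± 5.26, 387 ± 30.8, 325 ± 50.1 and 356 ± 89.3 TPM, and CCL2 at 81.5, 40.3, 39.4 and 46.5 TPM. Over the list alone CCL2 fell with Pink1 siRNA and with Nrf2 siRNA (adjusted p = 0.0405 and 0.0199).

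The list calls rest on the preset correlation: 46 were made over the 7 comparisons and 0 held by camera with an estimated correlation, where the smallest adjusted p was 0.161. Median, mean and test had the same sign in all 46 called lists and differed in 18 of the 108 that were not called. DDIT4 rose with Nrf2 siRNA as well, from 21.4 ± 1.83 to 47.0 ± 10.1 TPM (adjusted p = 0.0248), while its list had an adjusted p of 0.0744. Of the genes named by rule as called, those called in every leave-out numbered 12 of 27 with Pink1 siRNA, 6 of 31 with Nrf2 siRNA and 10 of 34 with the double siRNA. They were 0 of 6 for the double siRNA against Pink1 siRNA, 1 of 2 against Nrf2 siRNA and 5 of 10 for Pink1 siRNA against Nrf2 siRNA. Outside the comparisons with scramble, only genes named by the size of their change were counted. Members named there from a list alone, such as IFI6 and TXNRD1, were not. HMCN1, TYRP1, SLC7A8, CP and CHRDL1 were among them with Pink1 siRNA, SCHIP1, IGFBP5, SCG2, NQO1 and MMP2 with Nrf2 siRNA, and IGFBP5, P3H1, YBX3, SCG2 and NQO1 with the double siRNA.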

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

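The tests of the interferon genes, of the most abundant gene, of the shared controls and of other splits of the samples were chosen after the results they bear on were seen; the test with the double-siRNA samples out of the fit and that gene removed was set before its result was seen. The interaction singled out 5 lists at the preset correlation, and none with an estimated correlation (adjusted p = 0.790 each). The mean log2 interaction, the double siRNA against the sum of the single siRNAs, was -0.43 for RPE identity genes, -0.94 for interferon-stimulated genes, 0.17 for OXPHOS genes, 0.26 for cholesterol synthesis genes and 0.14 for ribosomal protein genes. Of single genes limma called 0, and 753 had an unadjusted p under 0.05. Without scramble replicate 1 the interferon list was not called (-0.36), nor without Nrf2 siRNA replicate 2 (-0.40). The RPE identity list was not called without double-siRNA replicate 1 (-0.33), the OXPHOS list without Nrf2 siRNA replicate 2 (0.058) or double-siRNA replicate 3 (-0.028), and the ribosomal list without scramble replicate 3 (0.069), Pink1 siRNA replicate 2 (0.11), Nrf2 siRNA replicate 2 (-0.027) or double-siRNA replicate 3 (-0.081), nor with sample weights (0.096). The RPE identity call also ended with no filter (-0.27), the minimum of 5 TPM (-0.34) and technical replicate 1 alone (-0.36). Among leave-outs that kept the call, the means ranged further: the interferon mean was -1.42 without Nrf2 siRNA replicate 1 and -0.56 without double-siRNA replicate 1. The OXPHOS mean was 0.10 without scramble replicate 3, 0.26 without Nrf2 siRNA replicate 1 and 0.35 without double-siRNA replicate 1, and the cholesterol mean was 0.14 without Nrf2 siRNA replicate 2. The ribosomal mean was 0.092 and 0.22 without Pink1 siRNA replicate 1 and 3, 0.28 without Nrf2 siRNA replicate 1 and 0.34 without double-siRNA replicate 1.

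Interferon-stimulated genes were lower with Pink1 siRNA than with Nrf2 siRNA, by a median log2 fold change of -2.78. The list was called at the preset correlation, but not with an estimated correlation (adjusted p = 0.163). The median was -2.95 with the most abundant gene removed. That removal rescales all genes of a sample alike. The shares in these samples, 24.9% to 38.6%, were too alike for it to bring such a median near 0. Over the leave-outs the value nearest to 0 was -2.29, without Nrf2 siRNA replicate 2. The samples already lay at 0.85 or more with Nrf2 siRNA and at -0.50 or less with Pink1 siRNA, relative to the scramble mean. Both outcomes were thus fixed by values already seen, and neither adds independent support. Over 400 arrangements, the exact two-sided permutation p was 0.015 for Nrf2 siRNA (mean log2 difference 1.36) and 0.02 for Pink1 siRNA (-1.42). Adjusted over the 2 relations, the permutation p was 0.02 for both. That adjustment does not cover the other lists and comparisons, from which this list was chosen after its values were seen. The permutation p-values therefore describe the chosen list and add no independent support. A hypothesis left open is that the siRNAs may change interferon signalling through their targets. It may equally be the response of the cells to the siRNA molecules themselves, which differ between groups. Another siRNA sequence against the same target, or the target restored, would separate these, and the data hold neither. Also, scramble replicate 1 lay as low as the Pink1 siRNA samples.

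Rescaling the samples raised the number of called genes against scramble. For the double siRNA against Nrf2 siRNA it did not: 2 genes were called before and after median-of-ratios rescaling and quantile normalization. For the double siRNA against scramble, removing the most abundant gene gave 321 genes in place of 104, which goes with that gene's uneven share as a candidate explanation. For Pink1 siRNA against scramble, 149 genes were called with the double-siRNA samples out of the fit, and 261 with that gene removed as well, which argues against uneven double-siRNA samples as the whole cause. Why the share of that gene differs between samples was not tested, and no biological explanation was tested.

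Fold changes against scramble moved together. Of 100 simulations without effect, 27 gave a covariance as large for Pink1 siRNA and Nrf2 siRNA, 12 for Pink1 siRNA and the double siRNA, and 18 for Nrf2 siRNA and the double siRNA. The shared scramble samples could therefore account for the covariance across all genes. The simulations hold no changed gene, so calls, and with them shared calls, are rare in them by construction. They cannot tell whether the overlap, at the real numbers of calls, exceeds what the shared scramble samples give. The 8 and 25 higher genes that Pink1 siRNA shared with Nrf2 siRNA and with the double siRNA were reached in 0 of 100, and so were the 5 lower genes of the latter pair. The 19 higher and 10 lower genes of Nrf2 siRNA and the double siRNA were each reached in 1 of 100 simulations, and no other shared any (simulated means 8.92 and 2.55). For that pair the simulated means were 0 and 0 after median-of-ratios rescaling (59 and 32 called) and with the minimum of 5 TPM (26 and 12 called). Pink1 siRNA and Nrf2 siRNA shared 27 higher and 4 lower genes after that rescaling, and by limma 12 and 0 with that minimum. Pink1 siRNA and the double siRNA shared 69 and 25, and 29 and 7. What the siRNAs may have in common, biological or technical, stays untested.

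The 10 splits of 6 samples are too few for a share under 0.05: only the real split, 1 of 10, reached its own count in each comparison of groups. The real count and the highest of the other splits were 65 and 2 for Pink1 siRNA, 46 and 1 for Nrf2 siRNA and 104 and 2 for the double siRNA against scramble. They were 6 and 1 for the double siRNA against Pink1 siRNA, 2 and 1 against Nrf2 siRNA, and 137 and 1 for Pink1 siRNA against Nrf2 siRNA. Each other split mixes the compared groups, so any real difference between them widens the spread in that split. The low counts of the other splits are therefore no measure of what samples without effect would give. For the interaction limma called 0 genes (753 at an unadjusted p under 0.05), so each of the 100 splits reaches the real count by construction and the splits decide nothing; the highest other gave 4.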

How the results depend on the processing

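A pair of settings was chosen after seeing the data: the most abundant gene removed, and the double-siRNA samples out of the fit. The other settings were fixed before the data were examined. For the counts of Pink1 siRNA and the double siRNA against scramble that rise on rescaling, the tests of the cause are given above. The cause was not tested for the other changes given here. By design, leaving samples out, or fitting the compared groups alone, leaves fewer samples, and the fit of all 24 samples adds technical replicates alone. The depth is unknown, so what it limits cannot be computed. Where a left-out sample leaves 2 in its group, the spread is pooled over the groups. Numbers in parentheses after a list are its mean log2 fold change, and a sample is written by group and replicate, such as double 1. Calls of lists follow the test, whose direction can differ in sign from a mean near 0.

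With pseudocounts of 0.1 and 5, and with a minimum of 1.5-fold, no count moved by more than 1.5 times. Without a filter, 40 genes were called with Pink1 siRNA, 64 with the double siRNA and 79 for Pink1 siRNA against Nrf2 siRNA, of which 35, 61 and 75 were among the 65, 104 and 137. For the interaction, the minimum of 5 TPM gave 3. In the order Pink1 siRNA, Nrf2 siRNA and the double siRNA against scramble, double against Pink1 siRNA, Pink1 siRNA against Nrf2 siRNA, and interaction, median-of-ratios rescaling gave 171, 148, 333, 13, 296 and 2. Quantile normalization gave 215, 167, 295, 26, 342 and 2, and the most abundant gene removed 177, 128, 321, 21, 313 and 2. With the double-siRNA samples out of the fit, the count was 149 for Pink1 siRNA and 131 for Nrf2 siRNA.

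The compared groups alone gave 8 for Nrf2 siRNA, 6 for the double siRNA, 5 for Pink1 siRNA against Nrf2 siRNA and, by limma, 0 for the double siRNA against Pink1 siRNA and against Nrf2 siRNA, where the fit of all groups had 801 and 960 genes at an unadjusted p under 0.05. The replicate number as a block gave 40 for Pink1 siRNA, 30 for Nrf2 siRNA and 1 for the double siRNA against Pink1 siRNA, though the numbers were not seen to pair samples. Technical replicate 1 alone gave 40 for Pink1 siRNA, 21 for Nrf2 siRNA, and 1 for the double siRNA against either single siRNA. Technical replicate 2 alone gave 34 for Pink1 siRNA, 48 for the double siRNA, 0 for the double siRNA against Nrf2 siRNA and 76 for Pink1 siRNA against Nrf2 siRNA. The fit of all 24 samples adds technical replicates but no biological sample, with 1 correlation of 0.544 between them for all genes. A higher count there is therefore no added evidence. All 24 samples gave 434, 455 and 652 against scramble, 87 and 111 for the double siRNA against Pink1 siRNA and Nrf2 siRNA, 474 for Pink1 siRNA against Nrf2 siRNA and 28 for the interaction. Sample weights gave 814, 808, 3067, 2440, 1886, 1069 and 504 in the same order; their estimation stopped before it converged, with a weight of 11.4 for double 2, so nothing is rested on these counts. limma's treat against 1.2-fold gave 13, 6 and 17 against scramble, 1 for the double siRNA against Pink1 siRNA and 44 for Pink1 siRNA against Nrf2 siRNA.

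Leaving out single samples gave 22 to 40 genes for Pink1 siRNA, 6 to 31 for Nrf2 siRNA and 19 to 240 for the double siRNA against scramble. It gave 1 to 16 for the double siRNA against Pink1 siRNA (16 without double 1), 1 to 4 against Nrf2 siRNA, 35 to 174 for Pink1 siRNA against Nrf2 siRNA and 0 to 4 for the interaction. The lowest and highest counts were those without scramble 2 or 3 (22) and Pink1 1 (40), without Nrf2 3 (6), and without scramble 3 (19) and double 1 (240). The number of lists called was 2 to 7 for the double siRNA against Nrf2 siRNA (7 without double 1, 2 without double 2) and 2 to 9 for the interaction (9 without Nrf2 1, 2 without Nrf2 2). It was 0 in all 7 comparisons with an estimated correlation; for the double siRNA against Nrf2 siRNA it was 7 with no filter and 2 with the compared groups alone, and for the interaction 10 with all 24 samples.

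NFE2L2 and PINK1 kept their direction in all settings run. NFE2L2 was not called with the compared groups alone for Nrf2 siRNA (-2.03) or the double siRNA (-1.47), nor for the double siRNA with technical replicate 1 alone (-1.48) or without scramble 1, 2 or 3 or double 2, with -1.60 to -1.30 over the leave-outs. PINK1 was not called for the double siRNA with the compared groups alone (-1.54). Of 106 calls of named genes, 103 held with a pseudocount of 0.1, 99 with 5, 73 without a filter, 101 of 101 with the minimum of 5 TPM, 106 with either rescaling, 22 with the compared groups alone, 77 with the block, 61 and 66 with technical replicate 1 and 2, 99 with all 24 samples, 105 with the most abundant gene removed and 61 of 66 with the double-siRNA samples out. None reversed in these settings. Outside the comparisons with scramble, these calls cover only genes named by the size of their change, not members named from a list alone.

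For Pink1 siRNA against scramble, the lists whose call ended with an estimated correlation were RPE identity (0.49), OXPHOS (-0.18), interferon (-0.95), cholesterol (-0.17) and ribosomal (0.26). The minimum of 5 TPM lost RPE identity (0.35). The replicate block added ATF4 (0.17). Technical replicate 1 alone lost cholesterol (-0.14). All 24 samples added ATF4 (0.17). Sample weights added ATF4 (0.17) and cell cycle (0.14). Left-out libraries lost cholesterol (-0.19 to -0.15, without scramble 1). They added ATF4 (0.12 to 0.22, without scramble 2).

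For Nrf2 siRNA against scramble, the lists whose call ended with an estimated correlation were NRF2 targets (-0.44), mesenchymal (0.33), RPE identity (0.40), OXPHOS (-0.18), PI3K and AKT (0.13), cell cycle (-0.16), interferon (1.83), cholesterol (-0.23), glycolysis (0.54) and complement (0.37). A minimum of 5 TPM added epithelial (-0.22). Median-of-ratios rescaling added epithelial (-0.18), antioxidant (-0.15) and ribosomal (-0.10). Quantile normalization added epithelial (-0.18), antioxidant (-0.14), ATF4 (0.13) and ribosomal (-0.12). The replicate block lost PI3K and AKT (0.13). Technical replicate 1 alone added epithelial (-0.20) and lost PI3K and AKT (0.12). Technical replicate 2 alone lost PI3K and AKT (0.14). All 24 samples added epithelial (-0.15), antioxidant (-0.13), ATF4 (0.15) and ribosomal (-0.075). Sample weights lost PI3K and AKT (0.14). The most abundant gene removed added epithelial (-0.17), antioxidant (-0.14) and ribosomal (-0.093) and lost PI3K and AKT (0.11). Left-out libraries lost PI3K and AKT (0.090 to 0.16, without scramble 3, Nrf2 2 and Nrf2 3). They added epithelial (-0.25 to -0.085, without scramble 2 and Nrf2 3), antioxidant (-0.19 to -0.041, without scramble 2 and Nrf2 1), ATF4 (0.092 to 0.23, without scramble 2 and Nrf2 1) and ribosomal (-0.22 to 0.092, without scramble 2 and Nrf2 1).

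For the double siRNA against scramble, the lists whose call ended with an estimated correlation were NRF2 targets (-0.28), mesenchymal (0.52), RPE identity (0.45), OXPHOS (-0.20), ATF4 (0.18), glycolysis (0.46), complement (0.26) and ribosomal (0.33). The minimum of 5 TPM lost RPE identity (0.28) and complement (0.20). Median-of-ratios rescaling added cholesterol (-0.16). Quantile normalization added cholesterol (-0.17) and lost ATF4 (0.17) and complement (0.22). The compared groups alone lost complement (0.26). Technical replicate 2 alone lost ATF4 (0.17) and complement (0.24). Sample weights lost ATF4 (0.17) and complement (0.15). The most abundant gene removed added cholesterol (-0.25) and lost ATF4 (0.078). Left-out libraries lost OXPHOS (-0.39 to -0.017, without double 1), ATF4 (0.057 to 0.29, without scramble 1 and double 3) and complement (0.10 to 0.40, without double 3). They added cell cycle (-0.21 to 0.088, without double 3), interferon (-0.63 to 0.32, without scramble 1) and cholesterol (-0.20 to -0.045, without scramble 3).

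For the double siRNA against Pink1 siRNA, the lists whose call ended with an estimated correlation were NRF2 targets (-0.38), mesenchymal (0.47), cell cycle (-0.19), interferon (0.89), glycolysis (0.35) and complement (0.17). Quantile normalization lost complement (0.16). Technical replicate 2 alone lost complement (0.15). All 24 samples added ribosomal (0.065). Sample weights added epithelial (0.23) and lost complement (0.11). Left-out libraries lost cell cycle (-0.33 to -0.036, without double 1) and complement (0.017 to 0.29, without Pink1 2 and double 3). They added OXPHOS (-0.21 to 0.17, without double 3) and ribosomal (-0.16 to 0.27, without Pink1 3, double 1 and double 2). The sign turned for ribosomal (-0.16 without double 3).

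For the double siRNA against Nrf2 siRNA, the lists whose call ended with an estimated correlation were NRF2 targets (0.16), mesenchymal (0.19), interferon (-1.89) and ribosomal (0.41). No filter added antioxidant (0.11), cell cycle (0.098) and cholesterol (0.085). The minimum of 5 TPM lost mesenchymal (0.17). Median-of-ratios rescaling added antioxidant (0.12) and cell cycle (0.10). Quantile normalization added glycolysis (-0.15) and lost mesenchymal (0.11). The compared groups alone lost NRF2 targets (0.16) and mesenchymal (0.19). The replicate block added antioxidant (0.11) and cell cycle (0.098). Technical replicate 1 alone lost mesenchymal (0.18). All 24 samples added antioxidant (0.12) and cell cycle (0.10). Left-out libraries lost NRF2 targets (0.074 to 0.29, without Nrf2 3 and double 2) and mesenchymal (0.096 to 0.30, without Nrf2 2, Nrf2 3, double 2 and double 3). They added OXPHOS (-0.21 to 0.17, without double 1), antioxidant (-0.030 to 0.24, without Nrf2 1 and double 1), cell cycle (-0.048 to 0.25, without Nrf2 3 and double 1), cholesterol (-0.032 to 0.18, without Nrf2 1) and complement (-0.26 to 0.0054, without double 3). The sign turned for OXPHOS (-0.21 without double 3).

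For Pink1 siRNA against Nrf2 siRNA, the lists whose call ended with an estimated correlation were NRF2 targets (0.54), mesenchymal (-0.28), antioxidant (0.15), cell cycle (0.29), interferon (-2.78), glycolysis (-0.43), complement (-0.28) and ribosomal (0.34). A minimum of 5 TPM lost antioxidant (0.15). Quantile normalization lost antioxidant (0.13). Technical replicate 1 alone lost antioxidant (0.16). Sample weights lost antioxidant (0.10). Left-out libraries lost antioxidant (0.064 to 0.21, without Pink1 3, Nrf2 2 and Nrf2 3).

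For the interaction, the lists whose call ended with an estimated correlation were RPE identity (-0.43), OXPHOS (0.17), interferon (-0.94), cholesterol (0.26) and ribosomal (0.14). No filter lost RPE identity (-0.27). The minimum of 5 TPM added epithelial (0.29) and PI3K and AKT (-0.19) and lost RPE identity (-0.34). Median-of-ratios rescaling added epithelial (0.24). Quantile normalization added PI3K and AKT (-0.14) and glycolysis (-0.19). Technical replicate 1 alone added epithelial (0.30) and lost RPE identity (-0.36). All 24 samples added mesenchymal (0.14), epithelial (0.21), ATF4 (-0.14), PI3K and AKT (-0.18) and glycolysis (-0.19). Sample weights added epithelial (0.31) and lost ribosomal (0.096). The most abundant gene removed added epithelial (0.19). Left-out libraries lost RPE identity (-0.56 to -0.33, without double 1), OXPHOS (-0.028 to 0.35, without Nrf2 2 and double 3), interferon (-1.42 to -0.36, without scramble 1 and Nrf2 2) and ribosomal (-0.081 to 0.34, without scramble 3, Pink1 2, Nrf2 2 and double 3). They added epithelial (0.13 to 0.34, without scramble 2, Pink1 3, Nrf2 1, Nrf2 3 and double 3), ATF4 (-0.26 to -0.025, without Nrf2 1 and double 3), PI3K and AKT (-0.23 to -0.10, without scramble 1, scramble 2, Pink1 1, Pink1 3, Nrf2 1 and double 2), glycolysis (-0.28 to -0.075, without scramble 3, Pink1 1, Nrf2 1, Nrf2 3 and double 3) and complement (-0.35 to -0.10, without double 3).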

Other observations

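These genes were tested in each comparison like all others, but were chosen here after their values were seen. The small nuclear RNA RNU4-1 stood at 22319 TPM with scramble, 14566 with Pink1 siRNA, 18610 with Nrf2 siRNA and 10863 with the double siRNA, and RNU4-2 at 18820, 12265, 15486 and 10062 TPM. Of these, RNU4-1 was called lower with the double siRNA against scramble (adjusted p = 0.026) and RNU4-2 was not (adjusted p = 0.0551). Within the scramble group the interferon-stimulated gene IFIT1 ranged from 12.8 to 88.0 TPM, and ISG15 from 12.5 to 111 TPM.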
